A study of Mus musculus with 2 samples.

How the data were processed

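H3K4me1 was measured by chromatin immunoprecipitation and sequencing in kidneys of mouse embryos at embryonic day 16.5, in 2 biological replicates of 1 group, each a pool of embryos of both sexes. Replicate 2 was a pool of 41 embryos, and the size of the other pool was not stated. Each biological replicate combined 2 technical replicates, which the lists do not separate. The authors deposited 4 peak lists on mm10: 1 per replicate, 1 called on the alignments of both replicates together, and 1 of replicated peaks derived from the other 3. According to the deposited descriptions, peaks were called on filtered alignments against a control. The peak caller, its version, its thresholds and the aligner are not given in the sources used here, and no read counts were given, so depth is unknown and no interval that needs it was computed.

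Each peak in the deposited lists carried a fold enrichment over the control (a ratio), a -log10 p, a -log10 q and the offset of its summit in bp. These are the authors' own values, and they were used only to describe, rank or filter peaks within a list. The lists reached down to -log10 p values of 2.00 to 2.03, so weak peaks were kept by the authors. The share of peaks with a -log10 q of at least 2 was 75.6% in replicate 1, 84.8% in replicate 2, 86.2% in the pooled list and 96.0% in the replicated list. The replicate lists are made from 1 sample each, whereas the pooled and replicated lists draw on both, so the main values come from the replicated list and the spread (mean and SD, n = 2) from the replicate lists. The replicated list inherits the wider peaks of the pooled call, and its values can therefore lie above the replicate mean.

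Coordinates were checked against the GRCm38 sequence. No peak ran past the end of a chromosome. A single peak of the pooled list and 2 peaks of replicate 2 lay on an unplaced contig and were left out of the counts that need chromosomes. Genes and TSSs were taken from the basic GENCODE annotation of that build, with 21728 protein-coding genes and 41220 distinct protein-coding TSSs. Assembly gaps were left out of the lengths used for the genome, the chromosomes and the shifts, but not out of gene windows.

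Overlap between replicates counted a peak as shared when at least 50% of it or of its partner was covered. It was compared with 1000 circular shifts of the peaks within each chromosome in gap-free coordinates (one-sided). Location was given in bases, in the order promoter (within 1 kb of a TSS), exon, intron and intergenic, and compared with 1000 circular shifts (two-sided, Benjamini-Hochberg over 4 classes). The TSS profile gave the percent of TSSs covered at each distance. A promoter was CpG-rich when 500 bp around the TSS had a CpG observed over expected ratio of at least 0.6 and a GC content of at least 50%.

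Gene coverage was the percent of the gene body and 20 kb on each side covered by peaks. The 32 gene lists (7 of kidney cell types, 5 of other cells in the tissue, 7 of other tissues, 2 of controls, 6 of pathways, 3 of Hox groups and 2 receptor families) were fixed before the data were examined, as were the comparisons, the motifs and the main settings. Each list was compared with 10000 random lists of protein-coding genes of the same size, matched in 20 bins of window length (two-sided, Benjamini-Hochberg over the lists). The symbols Ahsp and Loricrin were not in the annotation. Genes within a list are not replicates, and neighbouring genes share windows. Random lists were drawn gene by gene, so for lists of neighbouring genes, such as the Hox lists, the p can be too small. The kidney genes and the genes of other tissues were compared by 100000 permutations of genes.

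The genes named in the text were set by a rule: 20 core kidney loci, the 3 most covered and the least covered gene of each kidney list, the most and least covered gene of every other list except the receptor families, the 10 strongest peaks and the 10 largest clusters. Clusters joined peaks within a fixed distance between 10 and 15 kb and were ranked by covered bases. X was ranked among 20 chromosomes by an exact test. Motif matches on both strands were counted in the central 500 bp of replicated peaks away from promoters, and in peak-free and gene-free windows 10 to 50 kb away with the same GC content in bins of 2%. The p came from 1000 swaps of peak and control windows within GC bins. Before matching, the median GC content was 47.8% in peaks and 44.0% in control windows.

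Alternatives changed 1 choice at a time: the overlap rule, a -log10 q of at least 2, the stronger 50% of peaks, promoter windows of 500 bp and 2.5 kb, summits in place of bases, 1 TSS per gene, windows of 5 kb and 50 kb, peak counts, removal of promoter peaks, matching on TSS number, joining distances, the central 200 bp, shuffled sequence, each replicate list alone and the pooled list. Random lists without receptor genes, and kidney lists without Hox genes, were added after the data had been seen. No peaks were called anew and no reads were used.

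The procedures were tested on simulated data. With partners planted for 60% of peaks, 60.1% of 19944 peaks were found shared, and 1 of 40 runs with independent lists had a p below 0.05. Peaks placed at promoters gave the planted 33.1% of bases, and 3 of 40 random sets passed. Lists of 15 genes with coverage raised by a factor of 2 were called in 70.5% of 200 runs, by a factor of 3 in 95.5%, and unchanged lists in 4.5%, so lists of this size with smaller differences would often be missed. A motif planted at 2 times its rate was recovered at 1.94, and a motif left alone at 0.952. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.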

Results

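The data describe where H3K4me1, histone H3 carrying a single methyl group on lysine 4, was enriched in the kidney of the mouse embryo at embryonic day 16.5. The mark is known from enhancers, active or poised, and from the flanks of promoters. Kidneys of embryos of both sexes of strain B6NCrl, a C57BL/6 mouse, were pooled, and chromatin immunoprecipitation followed by sequencing was carried out on 2 biological replicates, each from a separate pool. The pool of replicate 2 came from 41 embryos. There was 1 group and no second condition, so the comparisons were between the replicates, between peaks and matched positions of the genome, and between groups of genes within the tissue. At this age nephrons form at the edge of the kidney while podocytes and tubules mature further inside, so the tissue holds progenitors and differentiated cells side by side.

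The peak list of replicate 1 held 178155 peaks and that of replicate 2 held 204905. They covered 77.4 Mb and 93.3 Mb, with a mean of 85.4 ± 11.3 Mb (SD, n = 2). A list called on both replicates together held 177497 peaks over 101.1 Mb, and a list of peaks called replicated held 122900 over 86.7 Mb, which was 3.39% of the gap-free genome. Median peak width was 308 bp in replicate 1, 315 bp in replicate 2 and 519 bp in the replicated list. Median fold enrichment over the control, the value given by the authors, was 3.29 in replicate 1 and 3.41 in replicate 2. All coordinates are those of mouse build mm10 and count from 1. The number of reads behind each list was not given, so depth is unknown.

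The strongest H3K4me1 regions of each pool of kidneys nearly all overlapped a peak of any strength in the other pool, and the weaker ones often did not. Of the peaks of replicate 1, 116635 (65.5%, Wilson 95% interval 65.2 to 65.7) overlapped a peak of replicate 2 over at least 50% of either peak. Of the peaks of replicate 2, 110342 (53.9%, 53.6 to 54.1) overlapped a peak of replicate 1. After circular shifts of the peaks within each chromosome the shares were 4.99% ± 0.190 and 4.29% ± 0.162 (SD over 1000 shifts), and the one-sided permutation p was 0.001 in both directions, the smallest that 1000 shifts can give. In the strongest 10% of peaks by fold enrichment, 97.2% of replicate 1 peaks and 95.5% of replicate 2 peaks had a partner. In the weakest 10% the shares were 46.3% and 29.5%. Strong peaks were also wide, with median widths of 788 bp and 869 bp against 234 bp and 230 bp in the weakest 10%. The regions covered in both replicates measured 52.7 Mb, which was 68.1% of the covered bases of replicate 1 and 56.5% of those of replicate 2. Where at least 50% of each of the 2 peaks had to be shared, the shares with a partner were 39.5% and 34.4%. When only the stronger 50% of both lists were kept, the shares were 62.9% and 52.2%. Part of the partners of strong peaks therefore lay among the weaker peaks of the other list. With a -log10 q of at least 2 in both lists the shares were 68.8% and 50.9%. All intervals cover counting error only.

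**Figure D1:**
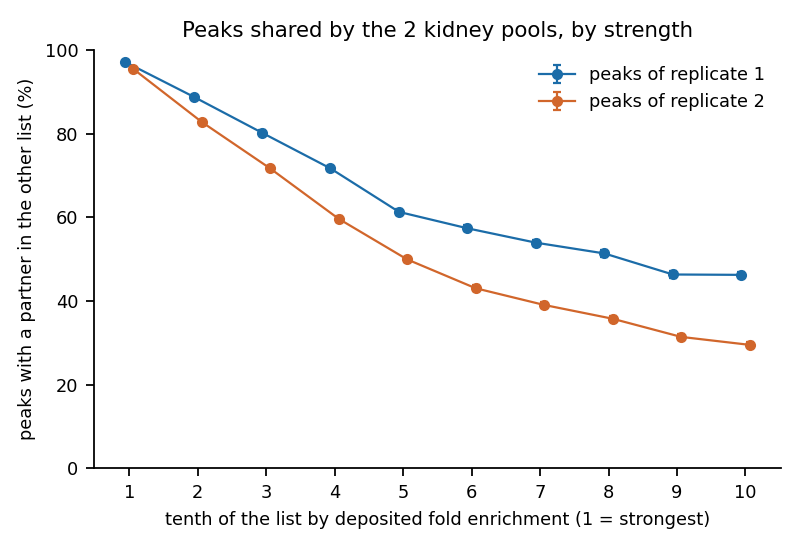
Percent of peaks with a partner in the other replicate (y axis) for 10 equal parts of each replicate's list ordered from strongest to weakest fold enrichment (x axis), with Wilson 95% intervals. Sharing fell from 97.2% to 46.3% in replicate 1 and from 95.5% to 29.5% in replicate 2.

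The replicated list was a subset of the pooled list. It held 122900 of the 177496 pooled peaks on the assembled chromosomes (69.2%). All 104832 pooled peaks that overlapped a peak of both replicates over at least 50% of either peak (59.1% of the pooled list) were in it, together with 18068 others. Replicate 1 alone supported 23789 pooled peaks by the same measure, replicate 2 alone supported 41638, and 7237 had support in neither. The pooled peaks outside the replicated list were weak and narrow, with a median fold enrichment of 2.65 and a median width of 238 bp, against 3.48 and 519 bp inside it. With at least 50% of each peak required, 38.5% of pooled peaks had support from both replicates.

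Strong peaks seen in 1 pool of kidneys alone were few and narrow. In the strongest 10% of replicate 1, 290 of 17815 peaks (1.63%, Wilson 95% interval 1.45 to 1.82) shared no base with a peak of replicate 2. In the strongest 10% of replicate 2, 626 of 20490 peaks (3.06%, 2.83 to 3.30) shared no base with a peak of replicate 1. Their median widths were 327 bp and 355 bp. The strongest in replicate 2 lay on chromosome 9 from 21225015 to 21225370, 13621 bp from the transcription start site (TSS) of Keap1, an adaptor that targets NRF2 for degradation, with a fold enrichment of 9.12. The strongest in replicate 1 lay on chromosome 5 from 148372087 to 148372493, 27639 bp from the TSS of Slc7a1, a transporter of cationic amino acids, with a fold enrichment of 6.41. Of these lone peaks, 285 and 609 overlapped a peak of the pooled list and 208 and 505 a peak of the replicated list. In the strongest 5% of each list, 40 and 107 peaks had no partner.

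Replicated H3K4me1 regions lay mostly inside genes, and their enrichment over shifted positions was highest within 1 kb of a TSS. Introns held 57.1% of the covered bases (57.3% ± 0.0288 in the replicate lists, SD, n = 2), against 42.7% after circular shifts, a ratio of 1.34. Positions within 1 kb of a TSS held 15.9% (replicates 14.9% ± 0.400) against 4.55%, a ratio of 3.49. Exons held 4.31% (replicates 4.29% ± 0.135), a ratio of 1.37, and intergenic sequence held 22.7% (replicates 23.5% ± 0.564) against 49.6%, a ratio of 0.458. The two-sided permutation p, adjusted over the 4 classes, was 0.002 for each, the smallest possible. With promoters taken as 2.5 kb around a TSS the exon ratio was 1.06 with an adjusted permutation p of 0.11. By summit, 16.4% of replicated peaks lay within 1 kb of a TSS, 36.0% at 1 to 10 kb, 44.3% at 10 to 100 kb and 3.34% farther away, and the median distance was 8.97 kb.

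The profile of the mark around protein-coding start sites differed between CpG-rich and CpG-poor promoters. At the 20361 TSSs in CpG-rich sequence, the class that includes most genes used in all cells, 7.51% of start sites were covered by a replicated peak (replicates 6.56% ± 0.0625, SD, n = 2). At 1 to 2 kb from these TSSs 33.5% of positions were covered (replicates 30.6% ± 2.88), which was 4.46 times the share at the start site (replicates 4.67 ± 0.394). Coverage was highest 1100 bp downstream, at 56.8%, and 94.4% of CpG-rich TSSs had a peak within 2 kb. At the 20859 CpG-poor TSSs, the class of many genes restricted to a tissue, the order was the opposite. Start sites were covered in 15.9% of cases (replicates 14.7% ± 1.24) and positions at 1 to 2 kb in 9.51% (replicates 8.96% ± 1.01), a ratio of 0.6, and 39.6% had a peak within 2 kb. Both differences from a ratio of 1 were larger than the spread between replicates, and no test was run on them.

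**Figure D2:**
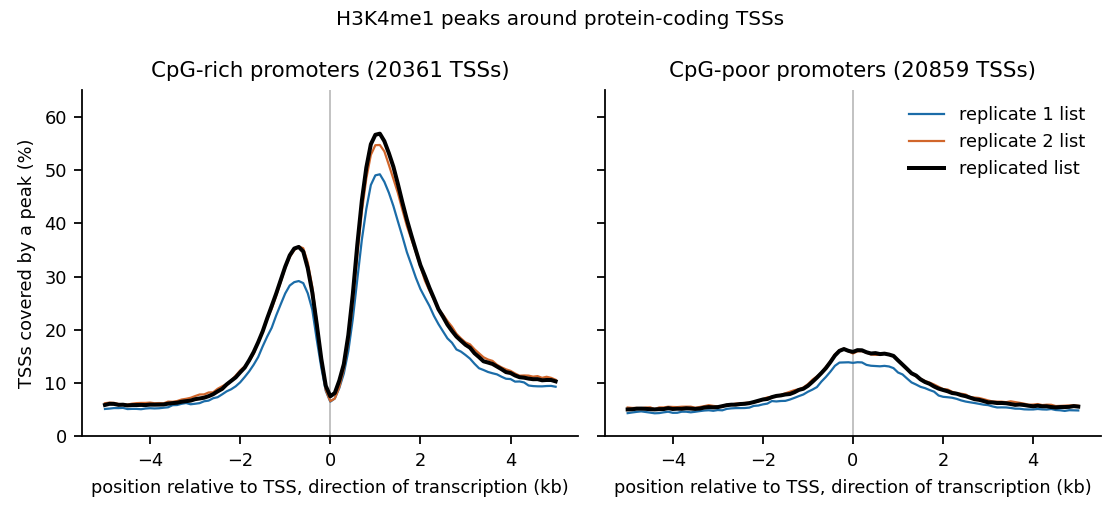
Percent of protein-coding TSSs covered by a peak (y axis) against the distance from the TSS in kb, downstream positive (x axis), for CpG-rich and CpG-poor promoters in the replicated list and in each replicate list. CpG-rich promoters dip to 7.51% at the TSS and reach 56.8% at 1100 bp downstream, while CpG-poor promoters are covered most near the TSS.

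Genes of the kidney carried more H3K4me1 than genes of other tissues. In the 102 genes of the 7 kidney lists a mean of 11.6% of the window, the gene body and 20 kb on each side, was covered by replicated peaks, against 5.25% in the 80 genes of the 7 lists of other tissues. The difference was 6.32 percentage points with a standard error of 1.24 over genes, and the means stood in a ratio of 2.20. The two-sided p was 1e-05 over 100000 permutations of genes, the smallest they can give. Genes were permuted singly although some neighbours, such as Clcnka and Clcnkb, share part of their windows. This p and the standard error can therefore be too small. The median gene of the kidney lists had 9.01% of its window covered and the median gene of the other tissue lists 2.76%. The difference was 5.51 in the list of replicate 1 and 6.17 in that of replicate 2. It was 3.66 (p = 0.00054, permutation test) when only the stronger 50% of peaks were used. Without the 3 Hox genes among the kidney genes, an alternative chosen after the data had been seen, it was 5.60 (p = 2e-05, permutation test). High coverage was not particular to kidney genes. Of the control lists described below, housekeeping genes had a higher mean than the kidney genes and cell cycle genes a lower one. No test compared these controls with the kidney genes.

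Among the kidney lists, the lists of progenitors, of early nephrons, of the ureteric tree, of stroma and of podocytes were covered more than random gene lists matched on window length, while the lists of mature tubule segments did not differ from them. All p values for lists are two-sided, come from 10000 random lists and are adjusted over the 32 lists tested. The list of the committing nephron, genes switched on as progenitors become epithelium, had 15.9% covered (replicates 15.1% ± 1.49, SD, n = 2), which was 2.34 times the random mean (adjusted permutation p = 0.0036). Of its 13 genes, 10 lay above the median of genes of similar length and 5 above the 90th percentile. Pax8, a transcription factor of the early nephron, had 33.0% covered (31.0% ± 2.08), Jag1, a Notch ligand, 27.4% (25.8% ± 3.26), and Wnt4, the signal of the transition to epithelium, 26.3% (22.4% ± 1.797). Cdh6, a cadherin of the early tubule, was lowest at 2.91%.

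The ureteric bud and collecting duct list had 14.9% covered (14.1% ± 1.22), 2.20 times the random mean (adjusted permutation p = 0.0045), with 13 of 15 genes above the median. Hoxb7 had 54.0% covered (52.3% ± 2.57), Wnt11, a signal of the ureteric tip, 28.0% (23.5% ± 1.96) and Wnt7b 18.9% (16.2% ± 1.57), while Calb1, which encodes calbindin, had 0.334% (0.287% ± 0.405). Nephron progenitor genes had 13.1% covered (12.49% ± 1.28), a ratio of 1.88 (adjusted permutation p = 0.028), with 12 of 15 above the median. Meox1, a homeobox gene, had 35.2% covered (32.9% ± 1.66), Hoxd11 28.4% (27.6% ± 3.13) and Sall1, a zinc finger factor needed for kidney formation, 23.3% (21.9% ± 1.48). Eya1, a coactivator that acts with SIX1 and SIX2, had 1.64% (2.34% ± 0.175). Hoxd11 and Hoxa11 in the progenitor list and Hoxb7 in the ureteric list lie in Hox clusters. Without them the progenitor list had 11.1% covered (adjusted permutation p = 0.14) and the ureteric list 12.1% (adjusted permutation p = 0.052).

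The renal stroma list had 12.0% covered (11.4% ± 0.972), a ratio of 1.90 (adjusted permutation p = 0.019), with 14 of 18 genes above the median. Its highest members were the homeobox genes Pbx1 at 30.02% (28.8% ± 2.52), Meis2 at 22.04% (20.7% ± 0.778) and Meis1 at 21.3% (20.3% ± 2.64), and Lum, which encodes lumican, was lowest at 2.48%. Podocyte genes had 12.0% covered (11.6% ± 1.198), a ratio of 1.87 (adjusted permutation p = 0.045), with 10 of 13 above the median. Synpo, which encodes synaptopodin, had 27.0%, Kirrel, a slit diaphragm protein, 25%, Foxc2 24.6%, and Magi2, whose window of 1518 kb was long, 0.353%. The strongest peak in the Foxc2 window lay in Mthfsd, 819 bp from a TSS. The proximal tubule list had 7.71% covered (ratio 1.15, adjusted permutation p = 0.67) and the loop of Henle and distal tubule list 5.01% (ratio 0.724, adjusted permutation p = 0.53). Within the proximal list the values ran from 24.3% at Ggt1, 23.6% at Pck1, an enzyme of gluconeogenesis, and 17.0% at Hnf1a to 0.366% at Hnf4a, which had more in both replicate lists (1.54% ± 0.489). Within the distal list they ran from 16.7% at Irx3, 13.6% at Clcnkb and 6.99% at Clcnka to 0 at Cldn16 (0.577% ± 0.289). The strongest peak of the Ggt1 window lay in an exon of its neighbour Lrrc75b.

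These calls for the kidney lists were sensitive to the window and to weak peaks. With 50 kb on each side of the gene the adjusted p was 0.064 for nephron progenitors, 0.052 for the committing nephron, 0.051 for stroma and 0.13 for podocytes. With the stronger 50% of peaks it was 0.11, 0.074, 0.18 and 0.14 in the same order. With olfactory and vomeronasal receptor genes kept out of the random lists, also an alternative chosen after the data had been seen, it was 0.057 for both nephron progenitors and podocytes. The podocyte list holds no Hox gene. Its adjusted value was 0.05 when Hox genes were left out of the other kidney lists, through the adjustment over the lists alone. The ratios stayed between 1.58 and 3.68 for these 4 lists in every alternative run.

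Signalling pathways that shape the kidney were densely covered. Their lists share members with the kidney lists, so the 2 sets of calls are not independent. These are Jag1 and Dll1 (Notch), Bmp2 (BMP and TGF-beta), Dkk1 (Wnt), Aldh1a2 (retinoid) and Gdnf, Ret, Etv4 and Etv5 (FGF and RET). The Notch list had 20.8% covered (19.8% ± 1.49), 3.04 times the random mean, the BMP and TGF-beta list 19.7% (18.9% ± 1.32), 3.02 times, the retinoid list 18.3% (17.4% ± 1.57), 2.92 times, and the Wnt list 16.5% (15.6% ± 1.46), 2.57 times. The adjusted p was 0.0008 for each, the smallest that the adjustment allowed, and each stayed below 0.05 in every alternative run. All 13 Notch genes, 21 of 22 Wnt genes, 13 of 15 BMP and TGF-beta genes and 10 of 11 retinoid genes lay above the median of genes of similar length. Members with the highest coverage were Rara, a retinoic acid receptor, at 50.2% (47.2% ± 4.39), Smad7, an inhibitor of TGF-beta signalling, at 48.2% (46.8% ± 1.62), Fzd4, a Wnt receptor, at 41.8% (37.7% ± 0.0667), and Notch1 at 38.0% (37.4% ± 0.401). The lowest were Rbpj at 3.85%, Bmp2 at 2.998%, Rspo3 at 2.86% and Aldh1a1 at 0 (0.348% ± 0.03003). The FGF and RET list had 12.1% covered (ratio 1.93, adjusted permutation p = 0.021), from 29.4% at Dusp6, a target of FGF signalling, to 1.02% at Fgf10. The Hedgehog list had 12.53% covered (ratio 1.92, adjusted permutation p = 0.044), from 25.7% at Ptch1, the Hedgehog receptor, to 2.91% at Hhip. With 50 kb on each side the adjusted permutation p of these 2 lists was 0.066 and 0.15, and with the stronger 50% of peaks 0.05 and 0.10. The Hedgehog p was also 0.065 with the list of replicate 2, 0.059 with that of replicate 1, 0.05 with the pooled list and 0.066 without receptor genes in the random lists.

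Hox genes, which give positional identity along the body axis, had the highest mean coverage of the lists tested in paralogue groups 1 to 8 and 9 to 11, but not in groups 12 and 13. Paralogue groups 1 to 8 had 58.0% covered (54.0% ± 1.77, SD, n = 2), 7.67 times the random mean, and groups 9 to 11, which include the Hox11 genes needed for kidney development, 36.1% (34.6% ± 3.22), 4.89 times. The adjusted p was 0.0008 for both. Groups 12 and 13, used in the most posterior structures, had 14.2% (14.2% ± 2.17), a ratio of 1.82 with an adjusted permutation p of 0.24. Within the first set the values ran from 86.4% at Hoxa4 to 18.1% at Hoxd1, within the next from 58.9% at Hoxb9 to 20.9% at Hoxc11, and within the last from 26.4% at Hoxd12 to 4.29% at Hoxb13. Windows of neighbouring Hox genes overlap, and with overlapping windows counted once the ratios were 7.58 and 5.48. The random lists were drawn gene by gene and not in clusters, so the permutation p of the Hox lists can be too small.

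Lists of other tissues and of other cell types gave a background measured in the same way. Liver genes had 2.40% covered (2.52% ± 0.418), 0.343 times the random mean (adjusted permutation p = 0.028), and keratinocyte genes 1.05% (1.34% ± 0.487), 0.153 times (adjusted permutation p = 0.019). With 5 kb on each side the adjusted p was 0.23 for liver and 0.056 for keratinocytes, and with peaks near TSSs left out it was 0.11 and 0.092. For liver it was also 0.073 with 50 kb, and 0.05 with the pooled list and with the stronger 50% of peaks. The other 5 lists of tissues, central neuron (7.18%), skeletal muscle (9.38%), heart (3.64%), lung and gut epithelium (7.39%) and germ cell (3.95%), did not differ from random lists, with adjusted p values of 0.84, 0.48, 0.37, 0.82 and 0.37. Their highest members were Slc17a7 (14.8%), Tnnt3 (39.6%), Myh6 (8.87%), Cdx1 (21.3%) and Prm2 (11%), and the strongest peak near several of these lay in a neighbour, such as the Pdgfrb intron next to Cdx1 and the Socs1 exon next to Prm2. Apoa2 (8.42%) and Krt1 (3.85%) were highest among liver and keratinocyte genes. The lowest members were Slc17a6 (0.347%, replicates 0.710% ± 0.6999) and, at 0, Myh8, Nppa, Serpina1a, Fabp2, Krt5 and Tnp1.

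Genes of other cell types that a whole kidney can hold did not differ from random lists. Endothelial genes had 7.48% covered (ratio 1.12, adjusted permutation p = 0.73), macrophage and leukocyte genes 5.23% (0.776, 0.64), erythroid genes 6.14% (0.881, 0.83), adrenal and gonadal genes 5.06% (0.705, 0.59) and sympathetic and neural crest genes 6.11% (0.835, 0.73). Plvap, a protein of endothelial fenestrae, had 22.4% covered and Emcn 0.503%. In the other lists the range was from 20.6% at Cd68 to 0 at Lyz2, from 17.3% at Nfe2 to 0 at Hbb-bt, from 21.0% at Amh to 0 at Mc2r (0.429% ± 0.606), and from 20.0% at Gata2 to 0 at the X-linked Plp1. Random lists were not matched on chromosome and coverage was low on X, so X-linked members can lower the value of a list. The strongest peak of the Cd68 window lay in Eif4a1, 325 bp from a TSS, that of the Nfe2 window in an intron of Cbx5, and that of the Amh window in an intron of Plekhj1. Among the controls, housekeeping genes had 13.4% covered (12.7% ± 1.29), a ratio of 1.92 (adjusted permutation p = 0.028), from 34.8% at Rplp0 to 2.29% at the X-linked Hprt. Their adjusted p was 0.066 with 50 kb on each side, 0.076 with the stronger 50% of peaks and 0.077 without receptor genes in the random lists. Cell cycle genes had 9.57% (ratio 1.39, adjusted permutation p = 0.36), from 21.4% at Aurkb to 3.88% at Bub1. The strongest peaks of the Rplp0 and Aurkb windows lay in the neighbours Pxn and Tmem107. Those of the Hprt and Bub1 windows lay in introns of these genes themselves. Olfactory receptor genes had 0.162% covered and vomeronasal receptor genes 0.0743% (adjusted permutation p = 0.0008 for both), and 1046 of 1134 and 319 of 330 of them had no replicated peak in their window. Across all 21728 protein-coding genes the mean was 6.59% and the median 4.01%, and 4673 genes (21.5%) had no peak.

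**Figure D3:**
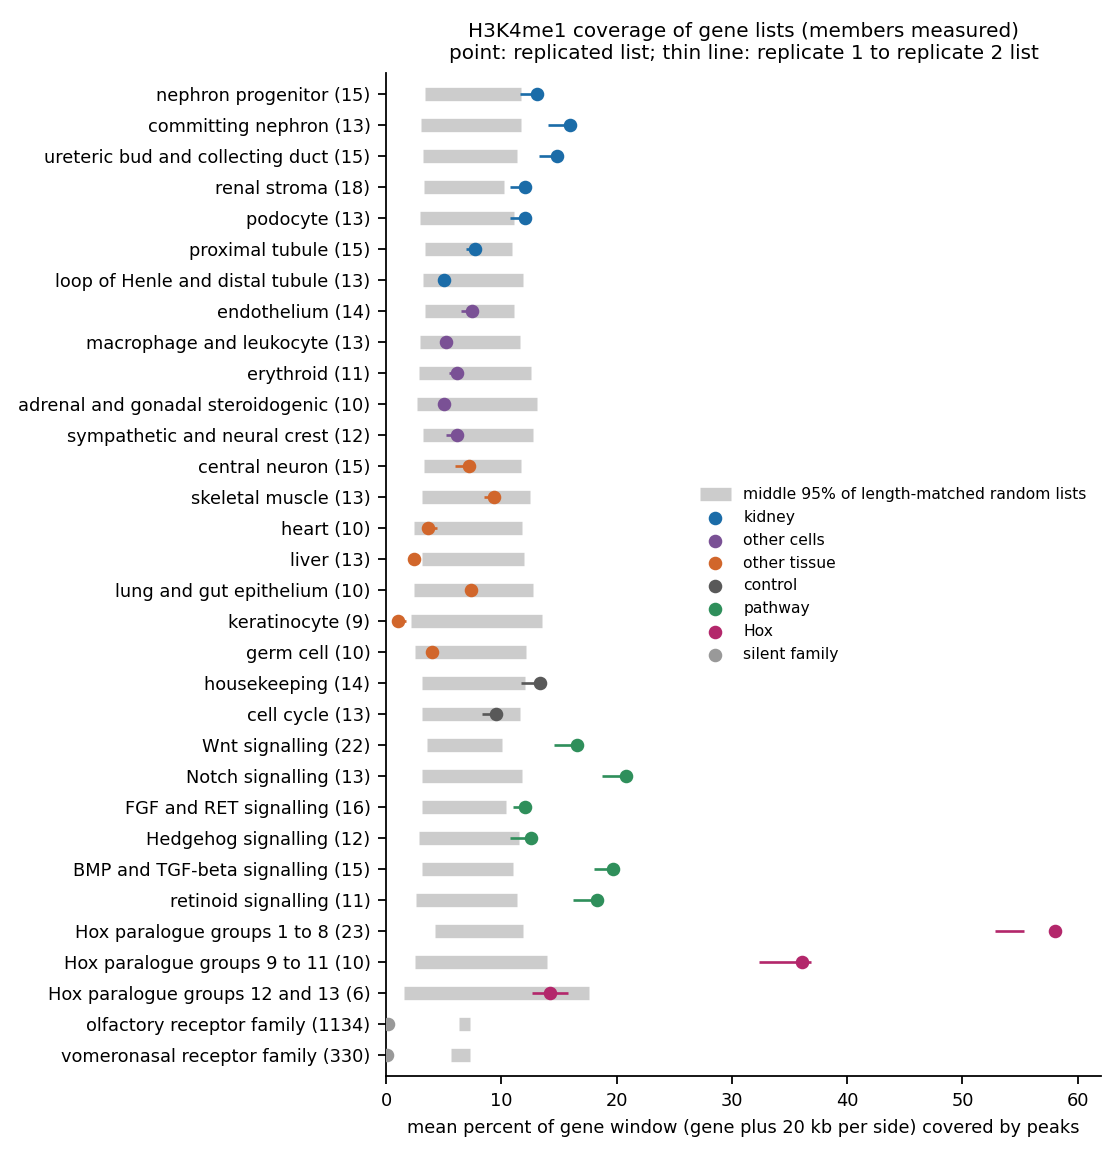
Mean percent of gene windows covered by peaks (x axis) for the 32 gene lists (y axis), with points for the replicated list, thin lines from the value of replicate 1 to that of replicate 2, and grey bars for the central 95% of random lists matched on window length. Hox groups 1 to 8 reach 58.0% and the Notch list 20.8%, while the keratinocyte list lies at 1.05%.

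Single loci of kidney development ranged from dense coverage to almost none. Over 20 core loci the mean was 12.3%, and 7 of them lay above the 90th percentile of genes of similar length. Pax8 (ENSMUSG00000026976, chromosome 2, 24420560 to 24475599, minus strand) had 36 replicated peaks in its window, against 54 in replicate 1 and 55 in replicate 2. The strongest, from 24415932 to 24418360 with a fold enrichment of 8.40, lay in the intergenic sequence between the 3' end of Pax8 and Psd4. Pax2 (chromosome 19, 44756045 to 44837871), a transcription factor of nephron and ureteric lineages, had 25.1% covered (23.9% ± 1.72) with its strongest peak at its 3' end. Wt1 (chromosome 2, 105126529 to 105173616), a factor of progenitors and podocytes, had 16.4% (15.2% ± 1.05), and its strongest peak lay upstream in Wt1os, 206 bp from an annotated TSS. The strongest peak of Wnt4 (chromosome 4, 137277489 to 137299726) lay in an intron from 137281662 to 137283942, 5485 bp from its TSS, with a fold enrichment of 7.57.

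Aqp2 (chromosome 15, 99579055 to 99584547), the water channel of the collecting duct, had 18.7% covered (16.8% ± 1.22) with a peak of 7.51-fold enrichment over its 3' end. Six2 (chromosome 17, 85684277 to 85688274), which keeps progenitors undifferentiated, had 9.76% (8.96% ± 0.841). Lhx1 had 12.7% (12.2% ± 1.75), Foxd1, a marker of stromal progenitors, 10.96% (11.3% ± 1.24), and Osr1 9.37% (8.36% ± 0.716). Gdnf, which calls out the ureteric bud, had 5.86% (6.29% ± 1.70), at percentile 59.8 of genes of similar length. Its receptor Ret had 3.01% (3.87% ± 1.09) and Hnf1b 3.24% (4.33% ± 0.976), at percentiles 42.1 and 44.3, so these 3 loci lay near the middle of such genes. Among genes of mature segments, Nphs1, which encodes nephrin, had 8.03% (8.30% ± 1.83), the phosphate transporter Slc34a1 5.82% (4.72% ± 0.670), the loop transporter Slc12a1 3.25% (3.44% ± 0.117), Umod 1.53% (1.28% ± 0.802) and Nphs2 0.757% (1.08% ± 0.141). Neighbouring genes held the strongest peak in several of these windows. It lay in Aatf for Lhx1 and in an intron of F12 for Slc34a1, and the only Nphs2 peak lay in Tdrd5, 274 bp from a TSS. Cells of each type are a part of the whole kidney, and a share of cells was not measured.

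**Figure D4:**
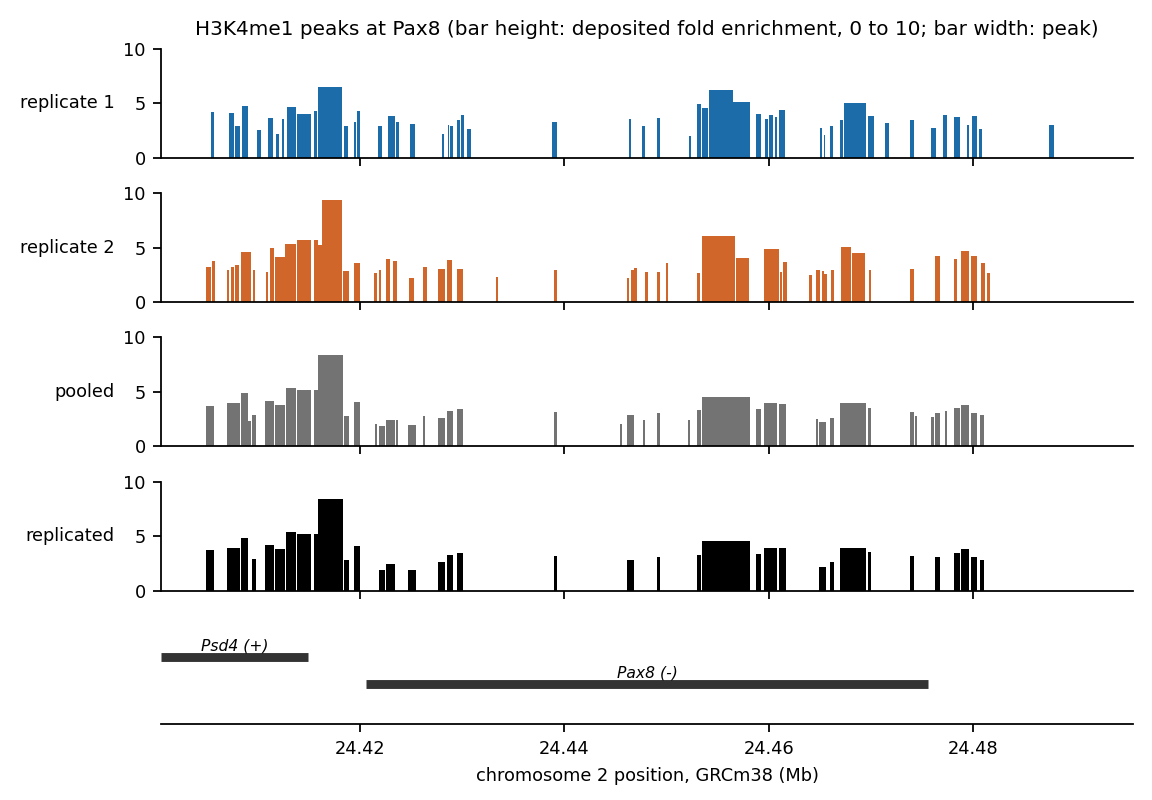
Peaks in the Pax8 window (chromosome 2, 24400560 to 24495599, x axis) in each list, with fold enrichment on the y axis and the positions of Pax8 and Psd4. The highest peak reaches 8.40 in the replicated list, 6.50 in replicate 1 and 9.32 in replicate 2.

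The largest clusters of H3K4me1 peaks covered single genes and regions of several genes, among them a region with Hoxc genes. Replicated peaks within a fixed distance of each other, between 10 and 15 kb, were joined. The cluster with the most covered sequence lay on chromosome 8 from 120169023 to 120641621, over Gse1, Gins2, Fam92b, 1190005I06Rik, Gm20388 and Gm27021. It had 139 peaks and 202.6 kb covered (replicates 190.2 ± 9.02 kb, SD, n = 2). The next were Msi2, which encodes an RNA-binding protein, with 160.4 kb (148.7 ± 6.54), and a region of chromosome 15 from 102934893 to 103259027 with 124.3 kb (114.9 ± 5.97). That region has 12 protein-coding genes, Hoxc4 to Hoxc12 and also Cbx5, Hnrnpa1, Nfe2 and Smug1. With peaks joined within 5 kb, a cluster over Hoxc genes alone had 54.3 kb covered. Tead1, a factor of the Hippo pathway, followed with 119.7 kb, and the region of Prrx2 and Ptges with 112.3 kb. Zmiz1 (110.4 kb), the chromatin remodelling gene Arid1b (105.7 kb) and Pbx1 (100.7 kb) came after these. A region of chromosome 10 with 22 genes around Stk11 (98.0 kb) and a region of chromosome 8 from 121148341 to 121403115 (97.6 kb) completed the 10. The only protein-coding gene that overlapped the latter was Gm20388, which also reaches into the largest cluster. This ranking depended on the joining distance. Only 4 of the 10 were among the largest with peaks joined within 5 kb, 3 within 3 kb, and 5 with the stronger 50% of peaks.

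The strongest replicated peaks were mostly intronic. The highest fold enrichment, 11.03, was found in an intron of Ncor2, a corepressor of nuclear receptors, on chromosome 5 from 125154567 to 125161115, and in an intron of Ahdc1 on chromosome 4 from 133019131 to 133027106. Further peaks lay in introns of Amotl2 (10.99), Dnmt3a (10.98), a DNA methyltransferase, Ncor2 again (10.9), Smad7 (10.6) and Csrnp1 and Cx3cr1 (10.6), 284 bp from a TSS of Sept9 (10.8), in Vcpip1 at 1336 bp from its nearest protein-coding TSS (10.6), and 2920 bp from the TSS of Tle3 (10.9), a corepressor of Wnt target genes.

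The X chromosome carried few H3K4me1 peaks. Replicated peaks covered 0.258% of the gap-free X, against 2.54% on chromosome 3, the lowest autosome, and 5.81% on chromosome 11, the highest. The mean over the 19 autosomes was 3.66% ± 0.831 (SD over chromosomes). The X value was 0.233% in replicate 1 and 0.354% in replicate 2. X ranked lowest of 20 chromosomes, with an exact permutation p of 0.05, the smallest that 20 chromosomes allow, so the test could not go below 0.05. There were 831 replicated peaks on X, or 5.08 per Mb against an autosomal mean of 51.6. No list had a peak on Y.

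**Figure D5:**
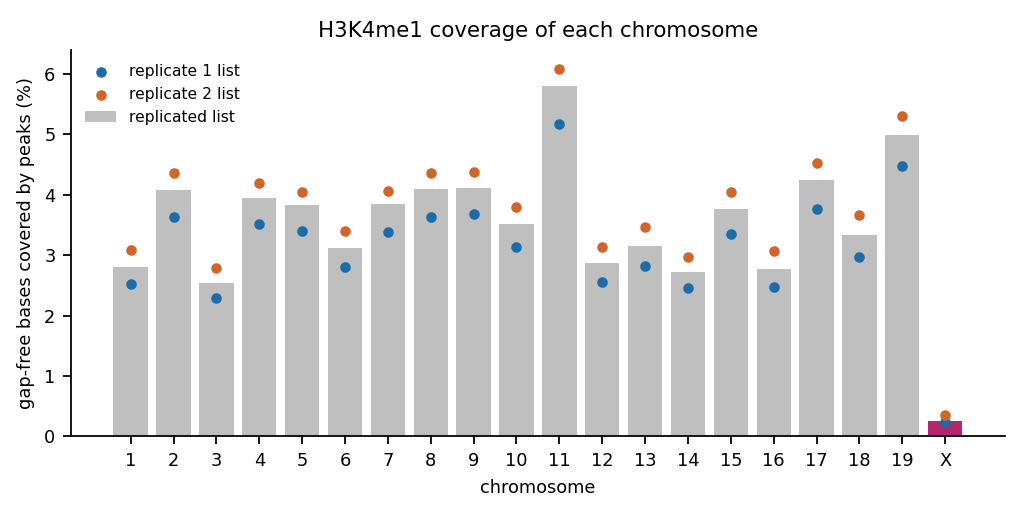
Percent of gap-free sequence covered by peaks (y axis) for 19 autosomes and X (x axis), in the replicated list and in each replicate list. X lies at 0.258% and the lowest autosome, chromosome 3, at 2.54%.

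Away from promoters, the centres of H3K4me1 regions held more matches to most of the motifs tested than GC-matched sequence. After GC matching, 69881 of 96787 windows of 500 bp were left. In these, 16 of 20 motifs had more matches than in control windows of the same GC content 10 to 50 kb away (two-sided permutation p, adjusted over the 20 motifs). The control windows were free of genes while many peaks lay in introns, so general differences between genic and gene-free sequence can enter these ratios. The highest ratios were those of HNF1, factors of nephron tubules, at 5.92 (77 against 13 matches), and NFI at 4.64 (102 against 22), both from few matches. HNF1 was at 4.06 with the list of replicate 1 and 5.41 with that of replicate 2, and NFI at 3.09 and 3.89. The HOX/PBX motif TGATTTAT had 2803 against 1372 matches, a ratio of 2.04 (1.88 in replicate 1 and 1.78 in replicate 2). MEF2 had a ratio of 1.87, WT1/EGR 1.77, the motif of SIX1 and SIX2 1.73, TEAD 1.51, FOX 1.45, TCF/LEF, the factors of Wnt signalling, 1.33, E-box 1.32, SOX 1.29, TFAP2 1.26, GATA 1.12 and AP-1 1.09. The adjusted p was 0.0029 for each of these, the smallest the adjustment gave. ETS (1.35, adjusted permutation p = 0.035) and RUNX (1.09, adjusted permutation p = 0.0053) also passed. CTCF (1.16, adjusted permutation p = 0.11), HNF4 (1.06, p = 0.32) and the nuclear receptor repeat DR1 (0.871, p = 0.36) did not, and PAX had 2 matches against 0 (p = 0.48).

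The control sequence mattered for some motifs. Against shuffled peak sequence with the same dinucleotides, the HNF1 ratio was 3.57 (adjusted permutation p = 0.0033) and DR1 had the highest ratio, 4.60, while WT1/EGR rose to 3.02 and ETS to 2.41. The NFI ratio there was 1.14 (adjusted permutation p = 0.72), SOX 1.01 (adjusted permutation p = 0.72) and AP-1 0.940 (adjusted permutation p = 0.011), while DR1 and CTCF (2.25) passed (adjusted permutation p = 0.0033 for both). In the central 200 bp CTCF was depleted, with a ratio of 0.5 (adjusted permutation p = 0.0031), NFI had a ratio of 3, and RUNX did not pass (adjusted permutation p = 0.11). With the stronger 50% of peaks AP-1, ETS and RUNX did not pass, with adjusted p values of 0.42, 0.98 and 0.088. CTCF passed with the lists of replicate 1 (1.45), replicate 2 (1.30) and the pooled list (1.35).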

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

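Random lists without receptor genes and kidney lists without Hox genes were the alternatives chosen only after the data had been seen. Of 112 alternatives to the 20 main results, 92 kept the direction and the side of the threshold, or stayed within the spread between replicates or within 1.5 times the main count. The share of pooled peaks supported by both replicates moved from 59.1% to 60.7% with an overlap of 1 bp, to 38.5% with 50% of each peak and to 54.2% with a -log10 q of at least 2. The exon ratio, 1.37, was 1.06 with promoters of 2.5 kb, where part of the exon sequence counts as promoter. The ratio of TSS flank to TSS was 2.10 with the stronger 50% of peaks and 1.79 to 1.89 in the replicate lists for all TSSs, 5.27 and 4.39 to 4.95 for CpG-rich TSSs, and 0.634 and 0.598 to 0.622 for CpG-poor TSSs, with 0.573 when 1 TSS per gene was used.

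Lists covered more than random lists numbered 14, but 7 with 50 kb on each side and 7 with the stronger 50% of peaks. Lists covered less numbered 4, and 2 without receptor genes in the random lists, where the receptor families were not tested. Of 382 alternatives for single lists, 349 kept their call, 31 lost it and 2 gained it, and none reversed. Kept calls include those of lists that passed neither in the main setting nor in the alternative. The 29 calls kept without Hox genes were nearly fixed in advance, because only 2 lists lost members. The gains were the germ cell list with 5 kb (adjusted permutation p = 0.013) and the macrophage list without promoter peaks (adjusted permutation p = 0.034), both below random lists. Strong peaks without a partner numbered 40 and 107 in the strongest 5% of replicates 1 and 2, and 503 in replicate 1 when a partner had to share 50%. Of the 10 largest clusters, 4, 3 and 5 were among the largest with joining at 5 kb, at 3 kb and with the stronger 50% of peaks. Of 120 alternatives for motifs, 107 kept their call, 6 lost it, 4 gained it and 3 changed direction. AP-1, which had passed, was depleted against shuffled sequence (0.940). DR1 against shuffled sequence (4.60) and CTCF in the central 200 bp (0.5) had no call in the main setting and passed in the other direction. For the other changes the cause was not tested. Coverage of the 89 named genes moved beyond the spread of the 2 replicates in 436 of 623 alternatives, so single-gene values hold for the stated window and list. Read depth was not given, so its effect on weak peaks is open.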

Other observations

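The tests of gene density and of the strongest peaks on X and of the use of genes at CpG-rich promoters, the comparison of X with scaled autosomal peaks and the choice of loci in the next paragraph came only after the results had been seen.

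Outside the Hox clusters, the most covered protein-coding gene was Cxxc5, which encodes a CXXC zinc finger protein. Its window had 61.2% covered (58.1% ± 1.30 in the replicates, SD, n = 2), and the widest replicated peak, 17945 bp on chromosome 18 from 35833863 to 35851807, lay over it. The next widest peaks were 14288 bp in an intron of Tns1, 14016 bp in Smad7, 13439 bp in Sema3f and 13418 bp in Lasp1. On X, coverage was highest at Bcor and Efnb1. Bcor, a corepressor gene, had 23.9% covered (20.4% in replicate 1 and 23.0% in replicate 2) and Efnb1, an ephrin gene, 14.6% (11.1% and 15.2%), while 626 of 948 X-linked genes had no peak. Among autosomes the share of genes without peaks ran from 10.2% to 33.5%, against 66.0% on X.

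CpG-rich start sites were covered less than their flanks, by 25.96 percentage points in the replicated list (24.1 ± 2.81 in the replicates), and high GC content as the whole cause is argued against by the 10% of CpG-rich TSSs with the lowest GC (median 54.6%), where the difference was still 21.4 (SD 2.00 between replicates), but it was 34.97 in the 10% with the highest GC, so a part that goes with GC stays open. A loss of peak calls in any CpG-rich sequence is argued against by 5138 CpG-rich windows more than 5 kb from a TSS, where the centre was covered more than the flank and the difference was -11.0 (SD 0.189). Among genes of the fixed lists with a CpG-rich TSS, the mean difference was 42.2 in 26 housekeeping and cell cycle genes, 3.11 in 56 kidney genes and -20.8 in 24 genes of other tissues, and controls exceeded other tissue genes by 63.0 points (standard error 12.47, p = 1e-05, permutation test, the smallest possible) and kidney genes by 39.1 (adjusted p = 0.00066). Counted per TSS, the difference in the lists of replicates 1 and 2 was 36.5 and 46.4 for controls, -1.90 and 8.14 for kidney genes, where the sign changed, and -10.8 and -17.4 for other tissue genes. H3K4me1 may lie beside the start site where a gene is active in most cells and on it at CpG-rich promoters little used in the tissue, but kidney and other tissue genes did not differ at the threshold (permutation p = 0.063) and expression was not measured.

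Peaks were sparse on X. Low gene density is argued against by the X gene windows, of which 0.623% was covered on average against 4.70% on the lowest autosome, and repeats by the X sequence outside repeats, of which 0.430% was covered against 3.44% on the lowest autosome. The 10 strongest X peaks had a median fold of 5.24, which was 0.701 times the mean of 7.48 in 1000 random draws of as many autosomal peaks and below the lowest draw, 6.47 (one-sided permutation p = 0.001, the smallest possible), so the shorter list alone did not give the lower values. A candidate explanation is that a single active X copy per cell lowers enrichment. A plain factor of 0.5 on autosomal peaks would leave 11.6% of them above a fold of 2.48, the low end of X peaks. The X density was 9.98% of the autosomal density. That cut was taken from the X peaks themselves and the caller's threshold is unknown, so the nearness of the 2 shares does not bear on the explanation. The peaks left would have a median fold of 2.80 where X had 3.26. The sex ratio of the pools and the handling of X in the control were not given, so this explanation and a difference in regulation of X both stay open.

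Kidney genes were covered more than genes of other tissues by 6.32 percentage points. The difference was 5.73 within CpG classes (p = 2e-05), 7.07 within 5 classes of window length (p = 1e-05) and 4.74 without transcription factor genes (p = 0.00094, permutation tests), which argues against each of these 3 as the whole cause. It was 9.01 among transcription factor genes alone (permutation p = 0.00037), and the difference between these and other genes was not tested. Here too genes were permuted singly although some neighbours share windows, so the p values can be too small. No biological explanation of the difference between kidney genes and genes of other tissues was tested.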
